A study of Nostoc sp. PCC 7120 = FACHB-418 with 6 samples.

How the data were processed

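The study measured which RNAs came down with a FLAG-tagged protein in Nostoc sp. PCC 7120 (also called Anabaena), a filamentous cyanobacterium that turns some of its cells into nitrogen-fixing heterocysts when combined nitrogen runs out. CLIP-seq sequences the RNA fragments that ultraviolet light has crosslinked to a protein and that are then pulled down with it. Per the labels' protocols, filaments were kept for 24 h without combined nitrogen, irradiated with 1.6 mJ/cm2 of ultraviolet light and lysed. Complexes were then captured on anti-FLAG M2 beads and eluted with FLAG peptide, and the protein was digested before the RNA was turned into libraries. There were 3 libraries from a strain carrying Alr1700 with a 3xFLAG tag and 3 from the untagged wild type taken through the same pull-down. Group and replicate number came from the sample titles. The labels give replicate numbers only and do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

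The values used were one table with 221 peaks for the whole series, each with replicon, start, end and strand, a value per library, and the authors' comparison. FastQC and Bowtie2 are named without a version in the submitters' processing notes. The peak caller, the counting tool, the normalisation tool and the genome build are not given in the sources used here, nor is whether peaks were called per library or on pooled libraries. The deposited value per peak and library is a signal: in each library all 221 values were whole multiples of one step, within a tolerance of 0.001 of a step, as for read counts divided by one size factor per library. The inverse of that step was taken as the size factor (1.16, 1.76 and 1.82 in tagged replicates 1, 2 and 3; 0.629, 0.783 and 0.549 in the untagged ones), and value over step as the number of reads. The authors' log2 fold change compares tagged with untagged libraries, per the file headers. The authors' p-value and adjusted p-value stand beside it, and the adjusted values have the form of a Benjamini-Hochberg adjustment over 3524 tests. Every listed peak had a deposited adjusted p of at most 1.00e-04 and a fold above 1, so the table is a selected list, and a test over it on the same libraries is not independent evidence. The regions that did not make the list were not analysed here. Positions are given as deposited, and the table does not say whether they count from 0 or from 1.

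The reads in peaks numbered 119086, 238993 and 179817 in the tagged libraries and 2560, 4021 and 2516 in the untagged ones. Total reads per library are not known, and the reads in peaks reflect enrichment as well as depth. Where the untagged libraries held 0 reads, the fold is a lower bound against 3 reads over the untagged group, which equals 1.53 normalised reads, written as "at least N-fold". Where they held 1 to 3 reads, the ratio of size-factor-scaled reads is given with its exact (Clopper-Pearson) 95% counting interval. The bound allows for counting error in the untagged reads alone and is less cautious than that interval: at the 63 peaks without untagged reads it was 1.12 to 1.32 times the exact lower limit of the ratio. Reads copied by PCR are not independent molecules, so intervals and bounds cover counting error only.

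Tagged and untagged libraries were compared with limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided) on log2(value + 1) as deposited, with Benjamini-Hochberg adjustment over the 221 peaks and a threshold of 0.05. Fold changes from this fit are on the log2(value + 1) scale and average logs over libraries. At all 125 peaks with at most 3 untagged reads they were below the deposited log2 fold change. At 50 of the other 96 they were above it, by at most 0.93. The plan had foreseen a count model for raw counts. The table holds normalised values, so limma was used and no count model was run. On simulated data with 3524 regions, 200 of them changed, the fit called 97.0% of regions changed 4-fold and 100% of those changed 16-fold. It called 100% of those changed 64-fold, and 0.211% of unchanged regions. Levels were drawn from the tagged means of the listed peaks, and both groups had the spread between tagged replicates. The untagged replicates correlated less well and held few reads, so these rates need not hold for the real comparison.

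Peaks were placed on the RefSeq gene table of assembly ASM970v1 (6169 genes). The chromosome carries the same versioned identifier in both. The plasmids carry identifiers in the peak table and names in the gene table, and which identifier belongs to which plasmid was taken from general knowledge and not checked against a source. Every plasmid name, plasmid gene neighbour and count per plasmid rests on that assignment. The gene table used here has no strand column. Strand was read from the locus tag, in which the letter before the digits is l for the reverse and r for the forward strand, for 5438 genes; the other 731 have no strand here. A peak was sense or antisense to a coding gene it overlapped by at least 1 nt, and an intergenic peak was placed upstream or downstream of a same-strand gene within 200 nt. RNA genes took precedence, then sense coding, antisense, pseudogene and coding genes of unknown strand.

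Gene lists were written from general knowledge before the data were examined, as were the tests, the other settings to be tried and the rule for named peaks. Of 18 lists, 13 could be matched by symbol, locus tag or gene type and were tested with Fisher's exact test, one-sided, of genes with a peak (antisense overlap excluded) against all annotated genes, with Benjamini-Hochberg adjustment over the 13. Overlap with a gene of unknown strand was counted. The carbon fixation list matched 0 genes. The lists of two-component and kinase regulators, transport, transposases and hypothetical proteins rested on product names, which the gene table used here lacks. The background is wider than the genes that could have given a peak, because unlisted regions were not analysed here, and no measure of transcript abundance was available to match on. In a test with 40 planted members of a list of 60 the planted list was recovered.

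Peaks were named by rule: the 10 with the largest deposited fold, the 10 with the smallest deposited adjusted p, the 5 with the highest mean in the tagged libraries, up to 10 in or within 200 nt of a member of the heterocyst differentiation, nitrogen fixation, nitrogen assimilation, RNA metabolism or sigma factor lists, any in alr1700, asr1701 or all1699, and the gene with the most peaks. The gene table used here places all1701 next to alr1700, and it was named as the gene with the most peaks. The rule gave 33 peaks. Position along coding sequences was tested with an exact two-sided binomial test of the first 50% and an exact Kolmogorov-Smirnov test of all midpoints, and shares carry exact 95% intervals. Alternatives were other pseudocounts (0.5 and 8), a minimum mean of 10, scaling to one total over the peaks, leaving out each library, the replicate number as a block, stricter peak thresholds, a 50% overlap, a 200 nt neighbourhood, merging peaks within 100 nt, and a background of coding genes. A comparison of base composition was planned and not run, since no genome sequence was used. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.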

Results

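Peaks of RNA recovered with a FLAG-tagged Alr1700 were compared with the same positions in an untagged control. The series title calls the protein PatR, an RNA-binding protein with an OB-fold-like domain and a regulator of heterocyst patterning, the spacing of nitrogen-fixing cells along the filament. There were 3 tagged and 3 untagged libraries, all from filaments kept for 24 h without combined nitrogen. The list held 221 peaks, 105 on the forward and 116 on the reverse strand, with a median width of 96 nt (range 27 to 183). Peaks lying within 100 nt of each other on one strand merged into 194 clusters. The peaks took up 119086 to 238993 reads per tagged library and 2516 to 4021 per untagged library. Levels below are normalised read counts, mean ± SD over 3 libraries.

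The first question was which RNAs were enriched in the tagged pull-down over the control. The highest level was at a reverse-strand peak between alr1199 and alr1200 (chromosome 1412992 to 1413131), with no annotated gene on its strand within 200 nt. It stood at 21847 ± 8308 in the tagged and 250.0 ± 16.4 in the untagged libraries. A forward-strand peak of 72 nt (chromosome 56432 to 56504), 114 nt upstream of trxA (alr0052, a thioredoxin gene) and 150 nt downstream of alr0051, reached 10405 ± 857 against 220 ± 19.9. It had the smallest deposited adjusted p of the list, 5.19e-53. The peak in ssrS, the gene of 6S RNA, which binds RNA polymerase (3340765 to 3340888), was also among the highest, at 12602 ± 2990, but stood at 2493 ± 601 in the control. Its log2 fold change of 2.34 ± 0.34 (SE) was the lowest of the list. It turned to -2.26 (limma adjusted p = 0.00141) when libraries were scaled to one total over the peaks. That scaling takes out the enrichment the peaks share, so the peak of lowest fold was bound to fall below 0.

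Other peaks high in both level and deposited significance lay mostly between genes. A reverse-strand peak (4768500 to 4768554) between alr3950, 170 nt away on the other strand, and a gene of unknown strand 105 nt away stood at 14946 ± 4419 against 252 ± 50.5. On plasmid beta, a forward-strand peak between all7659 and all7660 (164573 to 164693) stood at 5088 ± 723 against 89.6 ± 52.7, and on the chromosome a reverse-strand peak at 833539 to 833647, 53 nt from a gene of unknown strand, stood at 3607 ± 587 against 121 ± 41.7. On plasmid delta, a peak 108 nt downstream of alr8535 (27690 to 27761) stood at 2463 ± 692 against 28.5 ± 3.82. Smaller ones lay at 5603803 to 5603839 between cobM and lgt (931 ± 181 against 9.77 ± 3.73), 153 nt upstream of asr0148 (152679 to 152716; 844 ± 296 against 7.29 ± 1.58) and 119 nt upstream of miaE (3561608 to 3561721; 772 ± 79.2 against 9.10 ± 1.13).

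The peaks with the largest deposited fold had few or no reads in the control. Upstream of rppA (all7584) on plasmid beta (79138 to 79201) the tagged libraries held 173 ± 68.6 and the untagged ones no reads, so the peak was at least 113-fold higher (exact lower limit of the read ratio 90.7). Upstream of aroF (alr3050, named for a step of aromatic amino acid synthesis; 3692897 to 3692964) the level was 298 ± 79.0 with 1 untagged read, a ratio of 570 (counting interval 102 to 22545). On plasmid delta, between all8519 and all8520 (16196 to 16279), it was 217 ± 6.66, also with 1 untagged read, a ratio of 424 (76.0 to 16778). The other 7 had no untagged reads. The first was at least 70.6-fold higher, 4 nt downstream of all1872 and 65 nt upstream of all1871 (2234000 to 2234075). Others were at least 62.1-fold higher between alr3091 and alr3092 (3740164 to 3740216), at least 57.8-fold in alr0117 (119313 to 119412) and at least 55.2-fold antisense to all1865 (2228777 to 2228875). The rest were at least 55.0-fold higher between alr7325 and alr7326 on plasmid alpha (361384 to 361469), at least 54.5-fold in all3144 (3806709 to 3806781), and at least 54.1-fold in a plasmid alpha gene of unknown strand (303818 to 303905).

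**Figure D1:**
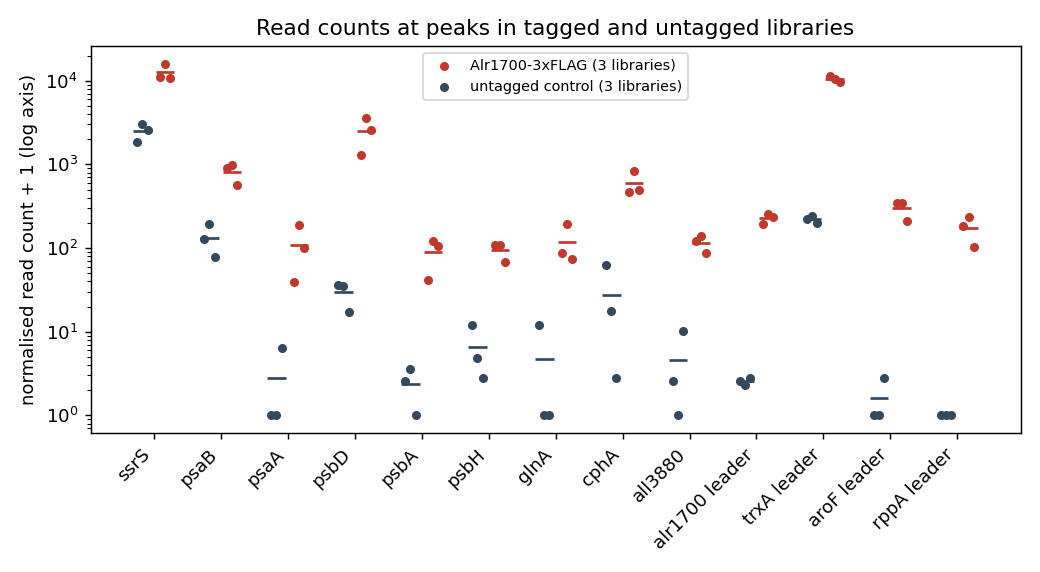
Normalised read count plus 1 (log axis) at 13 peaks in each of the 3 tagged libraries (red points) and the 3 untagged libraries (dark points), with the group mean as a bar; of several peaks in a gene the one with the smallest deposited adjusted p is drawn, and "leader" marks a peak upstream of the gene. Each tagged point lies above each untagged point of its peak. With libraries scaled to one total over the peaks, the log2 fold changes of ssrS (-2.26) and psaB (-1.92) turn below 0. That of psbH is then near 0 (-0.17, limma adjusted p = 0.833). The scaling takes out the enrichment that the listed peaks share, so peaks of low fold turn below 0.

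In limma all 221 peaks were higher in the tagged libraries, with a largest adjusted p of 0.00667, and log2 fold changes ran from 2.34 to 7.69 (median 5.42). The authors' deposited log2 fold changes had a median of 6.57 (quartiles 5.33 and 7.20; range 2.34 to 9.25). At 63 peaks the untagged libraries held 0 reads, and these were at least 21.7-fold to at least 113-fold higher (median bound 28.5). At 62 they held 1 to 3 reads. With those 63 peaks at their bound, the median log2 ratio of group means was 5.44. At all 221 peaks each tagged library exceeded each untagged one; chance separates 3 from 3 in this or the opposite way in 10% of cases. The list was selected on these libraries. With libraries scaled to one total over the peaks, 87 peaks stayed higher, 6 became lower, and the median log2 fold change moved by -2.10. That total is summed over peaks chosen as higher in the tagged libraries, so the scaling takes out the enrichment they share. It compares the peaks with one another, and a fold below 0 there does not mean a higher level in the control. The 87 were all 63 peaks without untagged reads, which on the log2(value + 1) scale shifted by only -0.92 to -0.87, and 24 of the 158 others, which shifted by -4.60 to -1.82. Of the 33 named peaks 11 then stayed positive but missed the threshold: those upstream of trxA, on plasmid beta at 164573, at 833539, in secE, cphA, all3880 and glnA, and opposite all1701 (at 2040288 and 2040482) and nifJ (both). Tagged strain and pull-down also cannot be separated, since no library of unselected RNA was analysed here.

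The next question was whether RNAs of heterocyst formation and nitrogen metabolism were among the peaks. A peak lay upstream of alr1700 itself, on its strand and 85 nt ahead of its start (chromosome 2039078 to 2039181), at 226 ± 31.8 in the tagged libraries. With 3 untagged reads its ratio was 151 (counting interval 51.4 to 732). Whether this segment belongs to the alr1700 transcript was not tested. The neighbouring all1701 carried more peaks than any other gene, 4, all on the opposite strand of the gene. The first (2040288 to 2040427) began 27 nt past the end of alr1700 and stood at 341 ± 41.9, against 5.53 ± 5.16 in the control; its limma log2 fold change of 6.29 (5.86 as deposited) was 6.97 without untagged replicate 2 and 5.22 without untagged replicate 3. The others stood at 92.5 ± 19.7 (2040482 to 2040562; 1 untagged read, ratio 176, interval 31.4 to 6959), 65.1 ± 5.79 (2040697 to 2040765; no untagged reads, at least 42.6-fold higher) and 91.4 ± 48.3 (2041204 to 2041322; 1 untagged read, ratio 184, interval 32.9 to 7286).

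**Figure D2:**
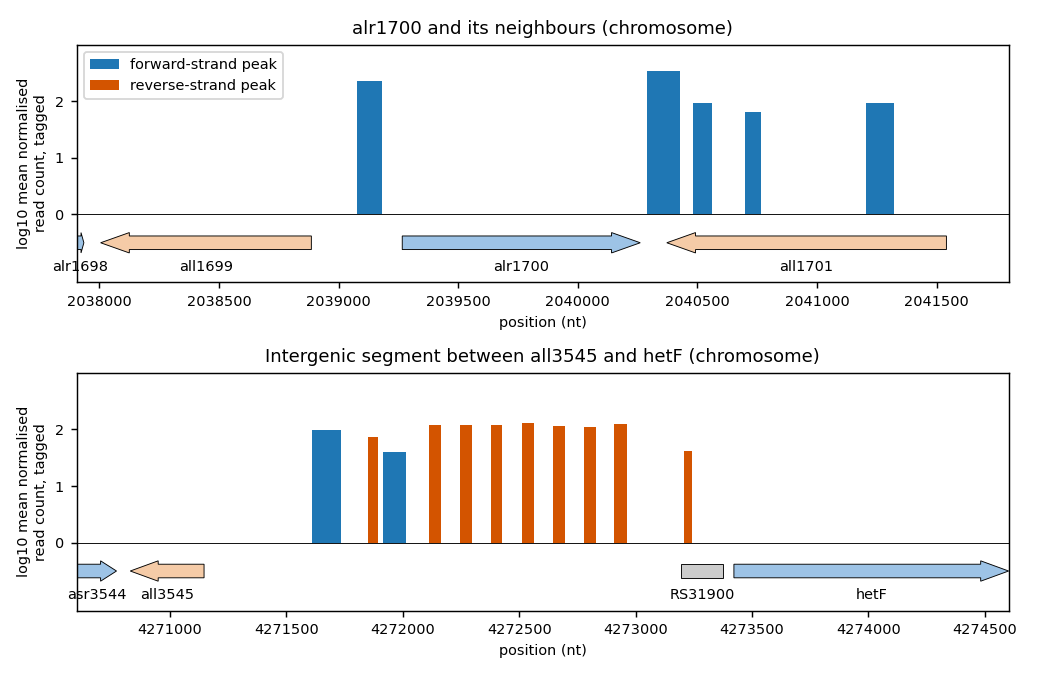
Maps of the chromosome around alr1700 (upper panel) and between all3545 and hetF (lower panel), with position in nt on the horizontal axis and the log10 mean normalised read count of the 3 tagged libraries as bar height; blue bars are forward-strand and orange bars reverse-strand peaks, and arrows show genes in the same colours (grey, strand unknown). The upper panel shows 1 peak ahead of alr1700 and 4 peaks behind it across all1701; the lower shows 2 forward-strand and 9 reverse-strand peaks ahead of hetF, and 7 of the reverse-strand ones stand 132 or 133 nt apart.

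No peak overlapped a coding sequence of the heterocyst differentiation and patterning list (0 of 21 genes), the heterocyst envelope list (0 of 29) or the nitrogen fixation list (0 of 20) on the sense or an unknown strand (Fisher's exact test, adjusted p = 1.00 for each). Within 200 nt, alr1700 was the only differentiation gene with such a peak (1 of 21). For a list with 0 genes, the one-sided test for enrichment can give no other p-value. Of the other genes, 1.46% to 1.47% had an overlapping peak, so lists this short would often have 0. The counts of 0 therefore do not show that these RNAs were not bound. A small reverse-strand peak (4273207 to 4273243; 41.9 ± 4.68, no untagged reads, at least 27.3-fold higher) lay over an annotated coding gene of unknown strand, 179 nt from hetF, a gene required for heterocyst differentiation that is on the forward strand. In nifJ (alr2803), which encodes a pyruvate:flavodoxin oxidoreductase, adjoining peaks lay on the antisense strand. They stood at 449 ± 234 (3411573 to 3411619; control 2.67 ± 2.73) and 67.6 ± 27.6 (3411620 to 3411671; 1 untagged read, ratio 124, interval 22.2 to 4934). The log2 fold change of the first, 7.17, was 6.42 without untagged replicate 1 and 7.76 without untagged replicate 3.

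Of the nitrogen assimilation list, 3 of 16 genes had a peak. In cphA (all3879, cyanophycin synthetase) it lay early in the coding sequence (4681206 to 4681316) at 601 ± 201 against 26.8 ± 31.4, and in the adjacent all3880, a cyanophycinase gene, late (4681919 to 4682043) at 115 ± 25.7 against 3.57 ± 4.87. In glnA (alr2328, glutamine synthetase) it lay near the 3′ end (2808739 to 2808859) at 117 ± 65.4 against 3.71 ± 6.43. The log2 fold changes of these peaks were 5.31 ± 1.09, 5.27 ± 0.83 and 5.55 ± 1.05 (SE), with limma adjusted p of 0.00244, 6.57e-04 and 0.00161. The deposited log2 fold changes were lower, at 4.48, 5.14 and 5.00. The limma values moved with single control libraries: the value for cphA was 6.37 without untagged replicate 1 and 4.13 without untagged replicate 3, and for all3880 4.48 without untagged replicate 2 and 6.15 without untagged replicate 3. For glnA it was 6.75 without untagged replicate 1, which held all of its untagged reads, and 4.95 without untagged replicate 2 or 3. Other genes had a peak in 1.41% of cases (Fisher's exact test, odds ratio 16.1, adjusted p = 0.00652). The test takes genes as independent, but cphA and all3880 are adjacent on one strand, so this p-value may be too small. Over the list's alternatives the adjusted p of Fisher's exact test ran from 0.00344 to 0.0483. With only peaks under a deposited adjusted p of 1e-06, cphA and all3880 alone remained (adjusted p = 0.0389).

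Photosystem genes had peaks in 5 of 38 cases: psbD, psbA and psbH of photosystem II, and psaA and psaB of photosystem I. The psbD peak (alr4548, the D2 reaction centre protein; 5442164 to 5442257) crossed the stop codon and was the highest, at 2477 ± 1137 against 28.6 ± 10.6. The psbA peak (alr3727, the D1 protein; 4500993 to 4501119) also crossed the stop, at 88.5 ± 42.2 with 3 untagged reads, a ratio of 61.9 (21.0 to 301). In psaB (alr5155) the peak (6155752 to 6155922) stood at 815 ± 218 against 133 ± 59.0. A peak over the start codon of psaA (6151385 to 6151468) stood at 108 ± 75.8 with 3 untagged reads, a ratio of 76.4 (26.0 to 372). Its log2 fold change of 5.60 was 6.20 without tagged replicate 1 and 6.49 without untagged replicate 3. The second psaA peak (6151475 to 6151604) stood at 239 ± 86.2 against 33.5 ± 15.2, a ratio of 7.81 (6.06 to 10.2), and the psbH peak (971460 to 971595) at 94.5 ± 23.3 against 5.60 ± 4.90, a ratio of 16.5 (9.11 to 33.2). Other genes had a peak in 1.39% of cases (Fisher's exact test, odds ratio 10.8, adjusted p = 0.00264). The psaA and psaB peaks lie near each other on one strand, so these genes may not be independent and the p-value may be too small. With libraries scaled to one total over the peaks, psaB (log2 fold change -1.92, limma adjusted p = 0.0175) and the second psaA peak (-1.74, adjusted p = 0.0317) turned below 0. The psbH peak was near 0 (-0.17, adjusted p = 0.833), psbA and the first psaA peak missed the threshold, and psbD stayed past it (adjusted p = 0.0402). That scaling takes out the enrichment all peaks share, so peaks of low fold turn below 0 by construction. With only peaks under a deposited adjusted p of 1e-06 the list had 2 genes (adjusted p = 0.106), and over its alternatives the adjusted p ran from 0.00173 to 0.106. The members other than psbD lie outside the naming rule and were chosen after their values were seen; the gene table used here has 5 psbA, 2 psbD, 2 psaB and 2 nifJ genes, between which reads could be divided.

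The non-coding RNA list had 6 of 86 genes with a peak against 1.38% of others (odds ratio 5.36, adjusted p = 0.00652). Apart from ssrS these were RNA genes of plasmid delta under 2 peaks, named after their values were seen. The strand of these genes and of ssrS is unknown here, so sense and antisense overlap could not be told apart. The 2 plasmid delta peaks lie on opposite strands. One (50917 to 51022) spanned 3 tRNA genes at 73.8 ± 42.2 with 1 untagged read, a ratio of 147 (26.3 to 5832), and the other (51510 to 51592) stood at 48.6 ± 4.50 with no untagged reads, at least 31.8-fold higher. The list's result depends on the overlap: it had 3 genes with a peak (adjusted p = 0.238) with at least 50% of the peak overlapping, and 13 (odds ratio 6.12, adjusted p = 1.73e-05) within 200 nt of the gene. Of those 13, 11 are neighbouring RNA genes of plasmid delta near the same 2 peaks. Fisher's exact test takes genes as independent, so its p-values for this list may be too small. With only peaks under a deposited adjusted p of 1e-06 it had 1 (adjusted p = 1.00). In the RNA metabolism list 0 of 6 genes had a peak, though one crossing the start of secE (6320767 to 6320878; 146 ± 56.8 against 3.23 ± 1.78), a protein translocase gene, ended 188 nt upstream of nusG, a transcription elongation factor gene. The remaining lists had 1 of 25 (ATP synthase and electron transport; atpB), 1 of 53 (ribosomal proteins; rplI), 0 of 4 (cell-cell joining), 0 of 6 (heterocyst respiration), 0 of 4 (phycobilisome) and 0 of 3 (sigma factors), all with an adjusted p of 1.00. For the lists with 0 genes that value was fixed in advance.

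The peaks were then sorted by the annotation around them. Between genes lay 101 of 221 (45.7%, exact interval 39.0 to 52.5), of which 24 were upstream and 15 downstream of a same-strand gene within 200 nt and 8 were between such genes. The other 54, among them the highest peak of the list, 164 nt from the forward-strand alr1200, had no gene known to be on their strand that near. Of these, 7 adjoined a gene whose strand is unknown, the peaks at 4768500 and 833539 among them. On the sense strand of coding genes lay 70 (31.7%, 25.6 to 38.2), and 18 were in coding genes of unknown strand. Antisense to coding genes lay 26 (11.8%, 7.83 to 16.8) over 22 genes, with all1701 and nifJ as the genes with more than 1. RNA genes and pseudogenes had 3 each. With only the 102 peaks under a deposited adjusted p of 1e-06, the counts were 62 intergenic, 21 sense coding and 8 antisense. The division depends on the overlap required: with at least 50% of the peak overlapping a gene, 127 (57.5%, 50.7 to 64.1) lay between genes, 51 were sense coding and 23 antisense.

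Position along the coding sequence was examined for the 51 sense peaks with their midpoint inside a coding gene. The first 50% of the sequence held 21 of them (41.2%, exact interval 27.6 to 55.8), which did not differ from an even division (exact binomial test, p = 0.262). The last 10% held 16 (31.4%, 19.1 to 45.9), among them psbA, psaB, psbH and glnA, against the 5.10 of even placement. The first 10% held 8 (15.7%, 7.02 to 28.6). Over all 51 midpoints, with no zone singled out, the positions departed from an even spread (exact Kolmogorov-Smirnov test, p = 0.0115). Of all sense peaks, 25 crossed a stop codon and 15 a start codon, 3 of them both. Only a stop was crossed by 22 and only a start by 12, which did not differ from an even division (exact binomial test, p = 0.121). That comparison was not planned, and the end zones and the Kolmogorov-Smirnov test were chosen after the positions were seen. These tests take peaks as independent, which peaks of one gene may not be.

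**Figure D3:**
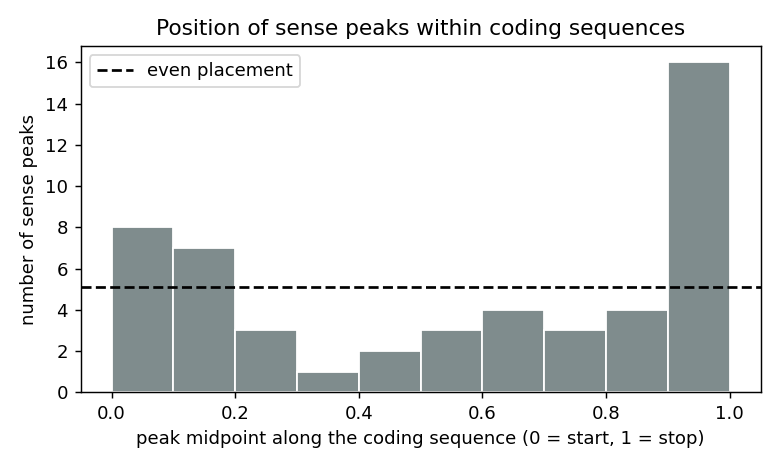
Number of sense peaks by the position of their midpoint along the coding sequence (0, start codon; 1, stop codon) in steps of 0.1, for 51 peaks; the dashed line marks even placement, 5.10 peaks per step. The last step holds 16 peaks and the first 8.

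Replicates were compared across peaks, which are not independent replicates. Pearson correlations of log2(value + 1) were 0.909 to 0.933 between tagged libraries, 0.729 to 0.796 between untagged libraries and 0.793 to 0.833 between the groups. Spearman correlations were 0.832 to 0.854, 0.553 to 0.652 and 0.661 to 0.737. The reads were unevenly spread: the 3 strongest peaks held 41.8% to 45.4% of the reads in peaks of each tagged library, and ssrS alone held 10.7% to 11.8% in the tagged and 45.5% to 59.3% in the untagged libraries. Of the 221 peaks, 108, 112 and 118 had no read in untagged replicates 1, 2 and 3.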

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

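The stricter threshold of 1e-06, the either-strand overlap, counting the peaks upstream of hetF once and removing the size factors were chosen after seeing the data. The count of 221 higher peaks held with pseudocounts of 0.5 and 8, a minimum mean of 10, size factors removed, an adjusted p under 0.01, and without each library in turn (221 to 221; largest adjusted p 0.0410). On a list selected on these libraries that count is at its maximum, so it shows nothing about stability. With libraries scaled to one total over the peaks it fell to 87, with 6 lower, and ssrS reversed to -2.26. That scaling takes out the enrichment the peaks share, so a fall in the count was to be foreseen. The 87 hold all 63 peaks without untagged reads, which shifted by only -0.92 to -0.87 on the log2(value + 1) scale, and 24 of the 158 others. The replicate block also left the count at 221 (largest adjusted p 0.0130). Same-numbered libraries did not deviate together (correlations 0.061, -0.012 and -0.044), and not every library correlated best with its own number. No pairing by number was seen, but with many untagged values at 0 this cannot show that there was none.

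The median log2 fold change was 6.57 as deposited, 5.42 on the log2(value + 1) scale, 6.18 with a pseudocount of 0.5 and 3.25 with 8, since a larger pseudocount shrinks peaks with few untagged reads. Without each library in turn the median on the log2(value + 1) scale ran from 5.29 to 5.56. At a deposited adjusted p under 1e-06 the deposited median was 6.13, against 6.57 for all peaks. That threshold left 62 intergenic, 21 sense coding and 8 antisense peaks, 2 photosystem genes (adjusted p = 0.106) and 1 non-coding RNA gene (adjusted p = 1.00); fewer peaks entered. Requiring 50% overlap left 3 non-coding RNA genes (adjusted p = 0.238), where counting peaks within 200 nt gave 13 (adjusted p = 1.73e-05; 11 of them near the same 2 peaks), and moved the classes to 127 intergenic and 51 sense coding peaks, against 101 and 70. The mean correlation between untagged libraries was 0.767, and 0.732 and 0.865 with pseudocounts of 0.5 and 8; the cause was not tested. Of the other values, 133 for main results and 422 for named peaks and classes counted as unchanged. They kept their direction and side of the threshold, stayed within 1.5 times (counts) or moved by at most an SD (medians and correlations). Many could not change, such as those for thresholds that removed no peak and for lists without a peak, so these totals show little about stability. Of the 33 named peaks, 5 moved by over 1.5 times without a single library, at most 2.30 times. Scaling to one total also took 11 named peaks below the threshold, and the 1e-06 threshold moved 4 counts of smaller feature classes. The planned thresholds of an adjusted p under 0.01 and of 4-fold removed no peak and show nothing about stability. The base composition test was not run for want of a genome sequence, and the alternatives for raw counts did not apply. Few untagged reads limit the size of the folds: 125 of 221 peaks had at most 3, and whether depth or lack of recovery is the reason was not tested.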

Other observations

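The tests of shared reads, of an RNA made only by the tagged strain, of random placement and of even placement along genes were chosen after the patterns were seen, as were the comparisons of replicons and of single peaks in this part. Peaks were unevenly spread over the replicons. Plasmid delta, with 0.770% of the annotated length, held 19 of 221 peaks (18 after merging peaks within 100 nt) where 1.70 would be in proportion, or 34.2 per 100 kb against 2.76 on the chromosome (exact binomial test over 7 replicons, adjusted p = 1.44e-13). This holds only if the identifier in the peak table was assigned to the right plasmid, which was not checked against a source. They included the peak downstream of alr8535, the tRNA peaks, and one upstream of alr8534 (25351 to 25399) at 144 ± 31.1 (n = 3) with 1 untagged read, a ratio of 274 (counting interval 49.0 to 10848). A peak ahead of ltrA, named for a group II intron protein (45744 to 45863), stood at 134 ± 2.77 with 2 untagged reads, a ratio of 131 (36.2 to 1087; limma log2 fold change 6.39, and 7.08 without untagged replicate 1), and another lay over its start (45927 to 46079; 52.3 ± 15.8, no untagged reads, at least 34.2-fold higher). Plasmid zeta held 2 (adjusted p = 0.0468) and plasmid gamma 0 against 3.12 in proportion (adjusted p = 0.144). Plasmid copy number and transcript abundance were not measured here.

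Upstream of hetF, between all3545 and hetF, 9 reverse-strand peaks lay from 4271849 to 4273243, the last of them over a coding gene of unknown strand. On the strand of hetF, 2 peaks lay between the same genes: 4271610 to 4271735 at 99.2 ± 26.7 (1 untagged read, ratio 194, counting interval 34.7 to 7695) and 4271913 to 4272012 at 39.7 ± 4.39 (no untagged reads, at least 25.9-fold higher). Of the reverse-strand peaks, 7 stood 132 or 133 nt apart from start to start, were 47 to 55 nt wide, and had tagged means of 112 to 132 with 1 to 5 untagged reads each. In a permutation test with the peaks of each replicon and strand placed at random, no window of 2000 nt in 1000 placements held 9 (p = 0.001, the smallest that many placements can give; highest 7), which argues against chance placement. Read numbers over the 7 varied no more than counting noise, with an index of dispersion of at most 1.12 in the tagged libraries against 6.91 to 9.63 for 17 other peaks of like level. That is consistent with reads divided among near-identical copies, so the 7 may stand for a single repeated RNA. A hypothesis is that this is NsiR1, a small RNA known to be encoded in tandem repeats upstream of hetF, but neither its coordinates nor the sequence were used here, and how many copies were bound stays open.

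The 4 forward-strand peaks across all1701 follow directly on alr1700. In the same kind of permutation test, 6 of 1000 placements put 4 or more peaks of one strand over a gene (p = 0.007). A window of 916 nt held 4 or more in 4 placements (permutation test, p = 0.005). With a window of 2000 nt it was 68 placements (permutation test, p = 0.069). That window could lie on any replicon, and plasmid delta had 34.2 peaks per 100 kb against 2.76 on the chromosome, where all1701 lies. The share for 2000 nt therefore need not hold for the chromosome. The 916 nt window is the span of these peaks' own starts, so its p-value may be too small, and chance placement stays open. A candidate explanation is a longer transcript of the tagged locus that only the tagged strain makes. The first peak had 12 untagged reads (exact Poisson interval 6.20 to 21.0), more than the 3 that a count of 0 allows. Untagged replicate 3 held 0 of these reads. They argue against an RNA wholly absent from the untagged strain only if they came from that strain's own RNA, which was not tested. Against 1586 tagged reads, they cannot show whether the tagged strain makes more of it. For the 3 inner peaks, with at most 1 untagged read, an RNA only the tagged strain makes cannot be told apart from binding of an RNA that both strains make. The reason is that 1 read lies within the 3 that a count of 0 allows. The peak upstream of alr1700, with 3 untagged reads, was not examined for this. The design's own difference, the tagged protein, stays open as well.

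For sense peaks near the 3′ ends of coding genes, even placement is argued against by the exact Kolmogorov-Smirnov p of 0.0115, which singles out no zone. With 51 midpoints drawn evenly at random, the fullest of 10 equal zones, wherever it lay, held 16 or more in 5 of 10000 draws. Both tests take midpoints as independent, which peaks of one gene may not be, so these shares may be too small. Merging peaks within 100 nt left 46 midpoints, 15 of them in the last 10%, but neither test was repeated on these. An end bias of the libraries that the control shares could give the same pattern. It was taken to lower the fold there, which need not hold if it raises both groups in the same proportion. The median deposited log2 fold change was 5.55 for the 16 peaks of the last 10% and 6.31 for the other 35, a difference of -0.76 (95% bootstrap interval -1.88 to 1.04). The interval covers both outcomes, so shared end bias and binding near stop codons cannot be told apart with these numbers.

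Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 221 peaks past the threshold in limma and the highest of the others 0, with 0 also at an unadjusted p under 0.05. The peaks were selected on the real split, with each tagged library above each untagged one at all 221, so this outcome was set in advance. It is no evidence against chance. Only 1 split gave as many, and 10 splits cannot give a share under 0.05 in any case.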
